A study of Mus musculus with 9 samples.

How the data were processed

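RNA was measured in 9 libraries from pancreatic islets of C57B/L6 mice aged 12 weeks. Per the labels' protocols, islets were isolated, picked by hand, cultured overnight, dispersed, stained for surface markers and sorted by FACS. The alpha-enriched subset was sorted as CD24 low and CD71 negative, the beta-enriched subset as CD24 low and CD71 positive, and the delta-enriched subset as CD24 high, with 3 libraries each. CD71 is the transferrin receptor, encoded by Tfrc, and CD24 is a surface glycoprotein encoded by Cd24a. Per the labels' protocols, total RNA was primed with random primers, libraries were made strand-specific with the NuGEN Ovation Solo kit, ribosomal RNA was depleted after amplification, and paired-end reads were sequenced on a NextSeq 500.

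The authors deposited 1 RSEM gene table per library and 1 normalised table of all libraries. Per the submitters' processing notes, STAR 2.5.2b, RSEM, R 3.5.1, DESeq2 1.22.1 and the genome build GRCm38.p6 were used, and the RSEM version is not given in the sources used here. Each deposited gene table held expected counts, TPM, FPKM and effective lengths for 55536 genes, per the file headers. RSEM shares reads that match several genes among them, and 6.94% to 8.66% of genes per library had an expected count that was not whole. The deposited FPKM values were not used in a test. The deposited normalised table, a signal per gene and library, held 17993 genes. Its values were tested on 8190 genes with over 50 counts in every library. In all 8190, within a relative tolerance of 1e-06, they equalled the rounded expected count divided by a size factor and by the relative effective length of the gene. All 55536 gene identifiers were matched to the GENCODE M21 annotation of GRCm38, from which symbols, biotypes and coordinates were taken.

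The unit of the main tests was the RSEM expected count, rounded to whole numbers. Library totals ran from 5663141 to 9529920 expected counts. Genes were kept by edgeR's filterByExpr with the subset as group, which left 15896 genes. TMM factors were computed, and edgeR 4.0.16 under R 4.3.3 was used for a robust quasi-likelihood fit of all 9 libraries with 1 coefficient per subset and no other covariate. The common biological coefficient of variation was 0.212, with 6 residual degrees of freedom and a median of 10.7 prior degrees of freedom. The 3 differences between subsets were tested 2-sided with Benjamini-Hochberg adjustment at 0.05. Every adjusted p for a gene in the comparisons is from edgeR unless another tool is named, and SE is the standard error of a log2 fold change. Levels are CPM, counts scaled to a common library total, after TMM scaling, as mean ± SD over 3 libraries.

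Genes enriched in 1 subset were defined by an intersection-union test. The larger of the raw p-values against the other 2 subsets was adjusted over all genes, and both log2 fold changes had to reach 1. Gene lists were tested with camera in limma 3.58.1 with an inter-gene correlation preset at 0.01, and again with an estimated correlation. Adjustment ran over 69 tests of lists and comparisons, since lists with fewer than 2 tested genes, those of endothelial, immune and erythroid cells, were not tested. The 26 lists came from textbook knowledge. Some genes stand in several lists, so the list results are not independent of each other. They covered markers of alpha, beta, delta, PP, acinar, duct, endothelial, immune, mesenchymal, Schwann and erythroid cells. They also covered iron uptake, storage and export, iron-sulfur cluster assembly, haem synthesis, islet transcription factors, hormone and nutrient receptors, glucose sensing and exocytosis, prohormone processing and granule cargo, and genes repressed in mature beta cells. The remaining lists held the unfolded protein response, citrate cycle, nuclear genes of the respiratory chain, glycolysis, cell cycle, immediate early and dissociation genes, and protein-coding genes of the mitochondrial genome. Counts of members past the test are given over all genes and adjusted over the list alone.

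Genes were named by a rule. Per comparison it took the 6 protein-coding genes with the largest rise and the 6 with the largest fall among those past the test, separated in all libraries and at 10 CPM or more in the higher subset. It also took the hormone and sort-marker genes Gcg, Ins1, Ins2, Sst, Ppy, Pyy, Iapp, Ghrl, Cd24a and Tfrc, up to 4 members past the test with the smallest p per list, and any member of the iron list. For enriched genes it took the 10 with the largest smaller fold change at 10 CPM or more. Some genes that the rule took are not reported here. Where a gene had 0 counts in the lower subset, the fold is a lower bound against 3 counts over that subset, and with 1 to 3 counts a ratio with a 95% exact counting interval is given. Counts were used as deposited and were not collapsed by molecular identifiers here, so these intervals and floors cover counting error only. 

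Alternatives were other scaling factors, other filters on low counts, hormone genes left out of library sizes, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a TPM of at least 1 in 3 libraries, fits of 6 libraries, the replicate number as a block, a test against a log2 fold change of 1, and each library left out in turn. No scaling factors between libraries were applied to TPM. Further settings were chosen after seeing the data. These left out ribosomal and 7S RNA genes, used effective-length factors in DESeq2, used limma on the deposited normalised values or on TPM rescaled without ribosomal and 7S RNA genes, left out beta replicate 2 and delta replicate 3, or left Tfrc out of the iron list. The edgeR steps were tested on simulated data for beta against alpha with 15518 genes, of which 200 with a mean of at least 50 counts were changed. The share of changed genes recovered was 23.9% at 1.5-fold, 77.6% at 2-fold and 95.5% at 4-fold, with 6 false among 137 calls. Recovery in genes with fewer counts was not simulated. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Nothing in the labels says whether libraries came from separate animals or pools, so p-values measure the spread among these samples.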

Results

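Each sorted subset carried mainly its own hormone transcript. Gcg, which encodes glucagon, stood at 89394 ± 9891 CPM in the alpha-enriched subset (mean ± SD, n = 3), against 393 ± 137 in the beta-enriched and 4380 ± 2159 in the delta-enriched subset. The insulin genes Ins1 and Ins2 were at 11154 ± 2068 and 25947 ± 4090 CPM in the beta-enriched subset, and Sst, which encodes somatostatin, was at 17221 ± 3226 CPM in the delta-enriched subset. Ins2 was also present in the alpha-enriched subset, at 2325 ± 395 CPM. Ppy, which encodes pancreatic polypeptide, was at 2014 ± 378 CPM in the alpha-enriched and 1709 ± 378 in the delta-enriched subset, and Pyy, which encodes peptide YY, was at 1245 ± 167 and 3395 ± 654. Both were low in the beta-enriched subset, at 41.5 ± 16.5 CPM for Ppy and 30.9 ± 2.41 for Pyy. Iapp, which encodes amylin, was highest in the beta-enriched subset, at 16532 ± 1503 CPM, and was also abundant in the delta-enriched subset, at 6202 ± 695. Ghrl, which encodes ghrelin, was below 1 CPM on average in every subset and was not tested.

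The transcripts of both sort markers differed between the gates by very unequal amounts. Cd24a (ENSMUSG00000047139, chromosome 10, 43578284 to 43584265) was at 868 ± 91.1 CPM in the CD24-high, delta-enriched subset and at 5.47 ± 2.11 and 3.56 ± 1.42 CPM in the alpha- and beta-enriched subsets (n = 3 each). Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794), which encodes CD71, was at 334 ± 24.6 CPM in the CD71-positive, beta-enriched subset, 209 ± 22.2 in the CD71-negative, alpha-enriched subset and 169 ± 26.6 in the delta-enriched subset. Tfrc was higher in beta than in alpha (log2 fold change 0.68, SE 0.11, adjusted p = 0.000196) and than in delta (0.99, SE 0.12, adjusted p = 3.38e-06). The difference between alpha and beta missed the threshold on log2(TPM + 1) and log2(TPM + 0.1). Between alpha and delta Tfrc did not pass (0.30, SE 0.11, adjusted p = 0.0634), though it passed without alpha replicate 2 (adjusted p = 0.0485) and without delta replicate 1 (adjusted p = 0.00419), with upper-quartile factors and with no filter on low counts. Both genes encode the proteins used for sorting, so their differences were no independent result. As shares of all counts, an exact two-sided permutation test of 3 against 3 cannot give a p under 0.1, which Gcg, Ins1, Ins2, Sst, Pyy and Iapp reached in all 3 comparisons. Tfrc gave 0.4 for beta against alpha, 0.2 for beta against delta and 0.4 for alpha against delta in that exact test. Its share was 0.0188% in beta replicate 2, against 0.0339% and 0.0360% in the other beta libraries. In beta replicate 2 a ribosomal RNA locus took 34.4% of all counts, which by itself lowers the shares of other genes, though some, such as Lars2, were raised there. In scaled CPM, Tfrc ran from 307 to 354 in beta, 188 to 232 in alpha and 148 to 199 in delta.

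**Figure D1:**
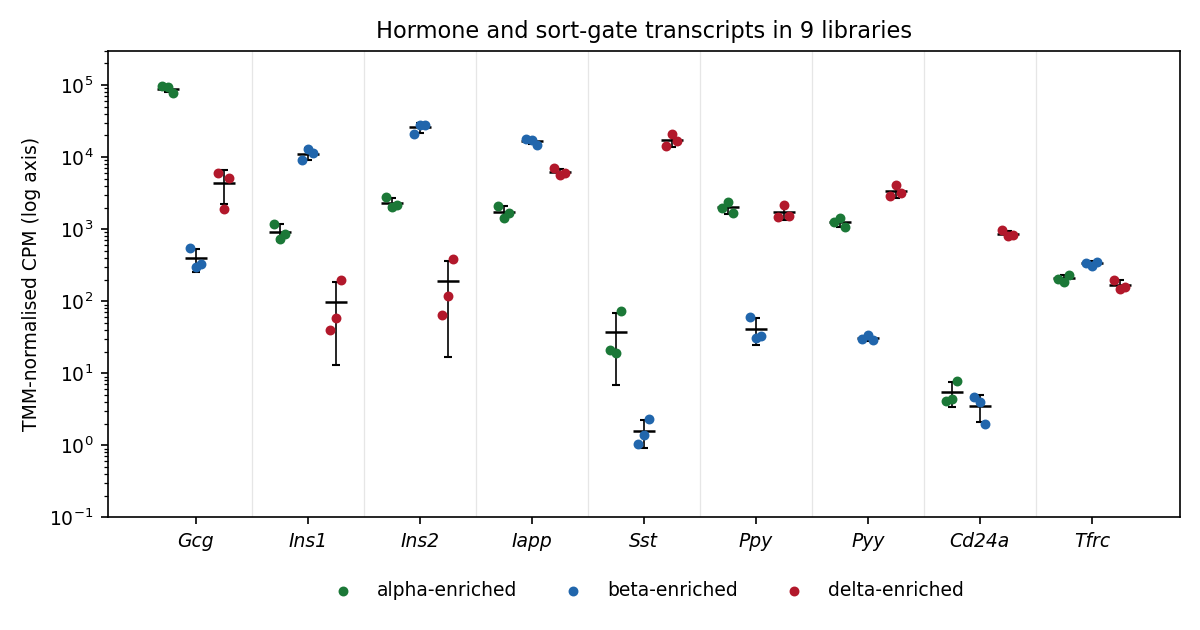
TMM-normalised CPM (log axis) of 9 hormone and sort-marker genes in the alpha-, beta- and delta-enriched subsets, with points for libraries, a bar at the mean and error bars of 1 SD (n = 3). Gcg averaged 89394 CPM in alpha, Ins2 25947 in beta and Sst 17221 in delta, while Tfrc spanned 169 to 334 CPM.

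Over all tested genes the libraries grouped by subset. The first principal component held 45.3% of the variance and parted beta from delta, and the second held 27.7% and parted alpha from both. Spearman correlations across genes were 0.974 to 0.976 among alpha, 0.982 to 0.986 among beta and 0.947 to 0.960 among delta libraries, and 0.866 to 0.911 between subsets. Genes are not independent replicates in these correlations. A pair of libraries stood apart. In beta replicate 2 the ribosomal RNA locus CT010467.1 took 34.4% of all counts, against 3.15% to 5.37% elsewhere, and protein-coding genes took 52.9%, against 79.0% to 82.2%. Lars2, named after its value was seen, took 2.28% there, against 0.0346% to 0.0926% elsewhere. Mitochondrial ribosomal RNA took 4.82%, against 1.37% to 3.63%. In delta replicate 3 the 12 acinar marker genes summed to 16303 counts, against 1186 and 971 in the other delta libraries. Alpha replicate 1 held 2617, against 375 and 455 in the other alpha libraries.

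**Figure D2:**
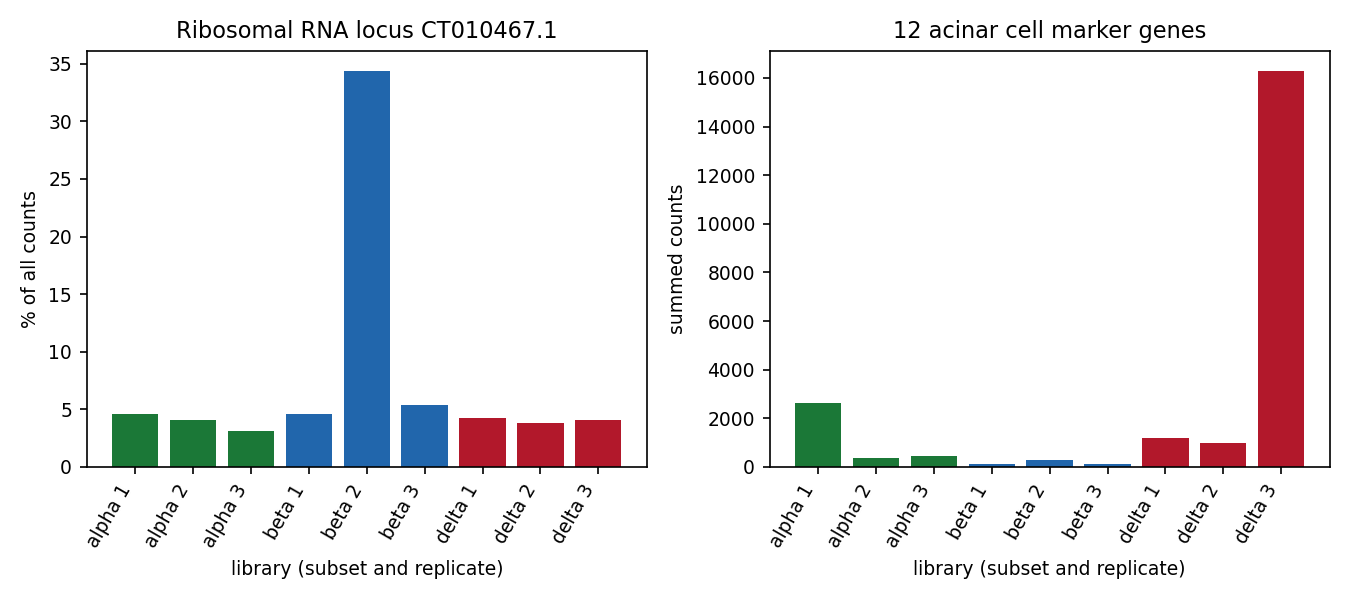
Share of all expected counts taken by the ribosomal RNA locus CT010467.1 (percent) and summed expected counts of 12 acinar marker genes, with 1 bar per library. CT010467.1 took 34.4% in beta replicate 2 and the acinar markers summed to 16303 counts in delta replicate 3.

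Between the beta- and alpha-enriched subsets, 4231 of 15896 tested genes differed, 2345 higher in beta and 1886 lower. More were higher in beta in every other setting but a pair, with 1959 higher and 2348 lower with upper-quartile factors and 552 and 659 in a test against a log2 fold change of 1. Glp1r, the receptor for glucagon-like peptide 1, was at 1095 ± 34.3 CPM in beta and 51.6 ± 11.3 in alpha (log2 fold change 4.41, SE 0.14, adjusted p = 6.12e-13, n = 3 each). Ucn3, a peptide hormone of mature beta cells (ENSMUSG00000044988, chromosome 13, 3940688 to 3945349), was at 209 ± 33.1 against 8.59 ± 0.880 CPM (4.61, SE 0.56, adjusted p = 0.00109). Irx2, a homeobox factor of alpha cells, fell from 124 ± 7.74 CPM in alpha to 1.02 ± 0.0216 in beta (-6.91, SE 0.20, adjusted p = 2.47e-13). Of the tested genes, 7239 (45.5%) had 3 libraries of beta entirely above or below those of alpha, where chance gives 10%, and 2145 of the genes past the test differed at least 2-fold.

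The largest differences with beta higher, by the naming rule, were in Th, the rate-limiting enzyme of catecholamine synthesis (6.24, SE 0.63), Cib3 (5.94, SE 0.71), Olfr1322 (4.97, SE 0.62), the cannabinoid receptor gene Cnr1 (4.88, SE 0.29), Ucn3 and Gm1043 (4.58, SE 0.38). Th moved to 7.74 without alpha replicate 2, Cib3 to 7.98 without alpha replicate 3 and 5.31 without alpha replicate 1, and Gm1043 to 5.35 without alpha replicate 3. The genes furthest lower in beta had 0 counts there. Ugt8a, a galactosyltransferase gene at 47.8 ± 9.58 CPM in alpha (ENSMUSG00000032854, chromosome 3, 125865271 to 125938619), was at least 317-fold lower. The others were Sertm1 (at least 92.3-fold), Igsf21 (at least 84.3-fold), Scin (at least 84.0-fold), the transcription factor Pou3f4 (at least 81.6-fold) and the adrenergic receptor gene Adrb1 (at least 68.1-fold). On log2(TPM + 1), where the added 1 compresses low values, Th came to 2.82 and Cnr1 to 1.63, with the calls kept.

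All 14 alpha cell markers were lower in beta (camera adjusted p = 2.43e-44), among them Etv1 (-3.73, SE 0.11) and the glutamate receptor subunit Gria3 (-2.60, SE 0.14). The call held with an estimated correlation (adjusted p = 0.00517). All 14 beta cell markers were higher (adjusted p = 3.08e-24), with adjusted p = 0.0614 with an estimated correlation. Examples were Papss2 (2.78, SE 0.11), Iapp (3.25, SE 0.14) and the transcription factor Nkx6-1 (2.42, SE 0.16). Ins1 (3.60, SE 0.66) and Ins2 (3.48, SE 0.69, adjusted p = 0.0114) are close paralogs, so the split of reads between them is uncertain. Without alpha replicate 2 or 3 Ins2 missed the threshold (adjusted p = 0.0528 and 0.0519). Of 7 delta cell markers, 3 were lower in beta, 1 was higher and 3 did not pass, with 4 lower adjusted over the list alone. Rbp4, a retinol carrier (-5.38, SE 0.20), and the fatty acid receptor gene Ffar4 (-4.52, SE 0.34) were lower, and Casr, the calcium-sensing receptor gene, was higher (0.51, SE 0.12), a call lost on log2(TPM + 1). Sst was lower in beta (-4.60, SE 0.80), at -3.69 without alpha replicate 3, and missed the threshold without beta replicate 2 and delta replicate 3 together. The delta list was lower (adjusted p = 8.21e-05, and adjusted p = 0.0373 with an estimated correlation). All 4 tested PP cell markers were lower in beta, Ppy (-5.59, SE 0.36) and Pyy (-5.34, SE 0.15) among them (adjusted p = 1.09e-12, and adjusted p = 0.00517 with an estimated correlation). The others were Sertm1 and Meis2 (-0.30, SE 0.10), and the call of Meis2 was lost without alpha replicate 3 (log2 fold change -0.21), beta replicate 1 (-0.29) or beta replicate 2 (-0.28).

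Genes of receptors, secretion and protein folding were mostly higher in beta. These lists share members with the marker lists, such as Glp1r, Trpm5 and Ero1lb of the beta markers and Ffar4 of the delta markers. Pdia4 stands in both the granule and the unfolded protein response list. The lists are therefore not evidence separate from the markers. Among 20 hormone and nutrient receptors 12 were higher, 5 lower and 3 without a call. Adra2a, an adrenergic receptor that restrains insulin release, stood at 2.77 (SE 0.15) and Igf1r at 2.03 (SE 0.12). The lower members were Sstr1, Sstr2, Ffar4, Gpr119 and Avpr1b, of which all but Ffar4 were named after their values were seen. The list was higher by the test (adjusted p = 0.000285, and adjusted p = 0.0388 with an estimated correlation), with a median log2 fold change of 0.77 and a mean of -0.23, which differ in sign. Of 17 genes of glucose sensing and exocytosis 11 were higher, 1 lower and 5 without a call, with 12 higher adjusted over the list alone. They included the cation channel gene Trpm5 (3.88, SE 0.28) and the calcium channel gene Cacna1d (0.61, SE 0.09), and the lower gene was the syntaxin gene Stx1a, named after its value was seen (log2 fold change -1.60). This list passed as higher (adjusted p = 0.00166), with adjusted p = 0.331 with an estimated correlation. Of 15 genes of prohormone processing and granule cargo 8 were higher, 4 lower and 3 without a call, with the convertase gene Pcsk1 at 2.94 (SE 0.17), Ero1lb, a beta cell oxidoreductase gene, at 2.83 (SE 0.19) and the granin genes Scg2 at 1.53 (SE 0.11) and Chga at 0.87 (SE 0.10). The lower ones, Pcsk1n (-1.02), Pcsk2 (-0.30), Pam (-0.49) and Scg5 (-0.49), were named after their values were seen, and Pcsk2 encodes the convertase that makes glucagon. By camera the granule list was higher (adjusted p = 0.00883), with adjusted p = 0.547 with an estimated correlation. On log2(TPM + 1), Cacna1d kept its direction and missed the threshold.

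In the unfolded protein response, 15 of 17 genes were higher in beta and 2 had no call (adjusted p = 2.25e-05, and adjusted p = 0.34 with an estimated correlation). Edem1, which sends misfolded proteins to degradation, stood at 2.16 (SE 0.15), and the chaperone genes Hyou1 at 1.03 (SE 0.13), Dnajb9 at 1.08 (SE 0.16) and Dnajc3 at 0.74 (SE 0.12). Of 20 citrate cycle genes 6 were higher and 14 had no call (adjusted p = 0.0151, and adjusted p = 0.364 with an estimated correlation), led by the pyruvate carboxylase gene Pcx (2.58, SE 0.17) and the fumarase gene Fh1 (1.19, SE 0.13). Among 9 tested genes known as repressed in mature beta cells, 5 were lower, 1 higher and 3 without a call. Oat (-4.91, SE 0.33) and the hexokinase gene Hk1 (-4.44, SE 0.68) were lower, and the catalase gene Cat, named after its value was seen, was higher (1.24). The list was lower (adjusted p = 0.00222), with adjusted p = 0.329 with an estimated correlation, and the call was lost under a stricter filter on low counts (adjusted p = 0.0574).

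Between the beta- and delta-enriched subsets 4869 genes differed, 2442 higher in beta and 2427 lower. The split stayed near even in most other settings, such as 2370 higher and 2458 lower with DESeq2 size factors in edgeR. It departed with upper-quartile factors (2122 and 2724), in a test against a log2 fold change of 1 (503 and 965), on log2(TPM + 1) (1198 and 815), on log2(TPM + 0.1) (1144 and 799) and on TPM rescaled without ribosomal and 7S RNA genes (2196 and 727), the last chosen after seeing the data. Ptprz1, a receptor tyrosine phosphatase gene (ENSMUSG00000068748, chromosome 6, 22875502 to 23052916), was at 355 ± 10.8 CPM in delta with 0 counts in beta, at least 2330-fold lower (n = 3 each). Hhex, a homeobox factor of delta cells (ENSMUSG00000024986, chromosome 19, 37434810 to 37440731), was at 203 ± 17.0 CPM in delta with 1 count in beta. Papss2, an enzyme gene of sulfate activation, was at 831 ± 16.1 CPM in beta and 32.7 ± 5.03 in delta (log2 fold change 4.67, SE 0.12, adjusted p = 6.35e-14). Nkx6-1 was at 299 ± 15.7 against 18.3 ± 5.68 CPM (4.03, SE 0.17, adjusted p = 6.88e-11). Of the tested genes, 6766 (42.6%) had groups that did not overlap, where chance gives 10%. Among genes at least 2-fold apart 958 were higher in beta and 1549 lower.

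By the naming rule, the genes furthest higher in beta were Slc7a15 (at least 108-fold), Mlph (at least 102-fold), Gm28048 (at least 77.2-fold), Lrrtm4 (at least 73.6-fold) and Col6a3 (at least 71.0-fold), all with 0 counts in delta. The sialyltransferase gene St8sia1 followed at 8.75 (SE 0.39), or 12.28 without delta replicate 3. Genes furthest lower were Ptprz1, Sst (-13.44, SE 0.92), Gpm6a (at least 795-fold), Gap43 (at least 236-fold), both membrane proteins of neurons, Hhex and the ghrelin receptor gene Ghsr. With 1 count in beta, the ratio of delta to beta was 3973 for Hhex (counting interval 712.7 to 157000) and 2883 for Ghsr (517 to 113900). The fitted log2 fold changes of both moved without beta replicate 3, from -11.54 to -13.55 for Hhex and from -11.06 to -13.07 for Ghsr.

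All 7 tested delta cell markers were lower in beta (adjusted p = 4.26e-21, and adjusted p = 0.004 with an estimated correlation), among them Rbp4 (-8.16, SE 0.20) and Ffar4 (-6.18, SE 0.32). All 14 beta cell markers were higher (adjusted p = 2.33e-31, and adjusted p = 0.0373 with an estimated correlation), with Glp1r at 2.87 (SE 0.13). Without delta replicate 3, Ins1 moved from 6.82 to 7.82 and Ins2 from 7.08 to 8.15. The 4 PP cell markers were lower (adjusted p = 2.91e-12, and adjusted p = 0.00517 with an estimated correlation), including Pyy (-6.78, SE 0.16) and Meis2 (-1.29, SE 0.10). Of 14 alpha cell markers 11 were lower in beta than in delta, 1 was higher and 2 had no call. Etv1 (-3.08, SE 0.11), Irx2 (-3.26, SE 0.23) and Gcg (-3.48, SE 0.50) were lower, and Slc7a2, a transporter of cationic amino acids, was higher (1.77, SE 0.15). The list was lower (adjusted p = 1.88e-07), with adjusted p = 0.154 with an estimated correlation.

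Receptor genes went both ways between beta and delta, and most called genes of the secretion lists were higher in beta. Among 20 hormone and nutrient receptors 10 were higher in beta, 8 lower and 2 without a call, with 11 higher adjusted over the list alone. Igf1r stood at 2.03 (SE 0.12) and Adra2a at 2.27 (SE 0.15), and Ghsr, Ffar4 and Casr were among the lower ones. The list was higher by the test (adjusted p = 0.0033, and adjusted p = 0.071 with an estimated correlation), with a median of 0.91 and a mean of -0.61, which differ in sign. In glucose sensing and exocytosis 9 of 17 genes were higher, 3 lower and 5 without a call. Cacna1d stood at 0.86 (SE 0.09), Snap25, a membrane fusion protein gene, at 0.75 (SE 0.10) and Cacna1c at 0.79 (SE 0.11). The lower genes, named after their values were seen, were Kcnj11 and Abcc8, which encode the ATP-sensitive potassium channel, and Stx1a. This list passed as higher (adjusted p = 0.00772), with adjusted p = 0.34 with an estimated correlation. In prohormone processing and granule cargo 6 of 15 were higher, 2 lower and 7 without a call, with Ero1lb at 5.49 (SE 0.22), Pcsk1 at 3.42 (SE 0.17) and Chga at 1.57 (SE 0.10), against Chgb at -1.12 (SE 0.10) and Pam, named after its value was seen. By camera the granule list was higher (adjusted p = 9.36e-05), also with adjusted p = 0.34 with an estimated correlation.

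In the unfolded protein response 10 of 17 genes were higher in beta than in delta and 7 had no call, and 1 was lower adjusted over the list alone. Edem1 stood at 1.75 (SE 0.15) and Trib3 at 1.49 (SE 0.26). The list was higher (adjusted p = 0.0119), with adjusted p = 0.586 with an estimated correlation and 0.114 without beta replicate 2 and delta replicate 3 together. Among 20 citrate cycle genes 11 were higher and 9 had no call, with Pcx at 4.08 (SE 0.19) and Fh1 at 1.61 (SE 0.14) (adjusted p = 0.000601, and adjusted p = 0.249 with an estimated correlation). Of 9 genes known as repressed in mature beta cells 5 were lower and 4 had no call, with 6 lower adjusted over the list alone. Oat stood at -2.50 (SE 0.35) and Cat at -1.85 (SE 0.38), whose call was lost on log2(TPM + 0.1). The list was lower (adjusted p = 0.0352), with adjusted p = 0.514 with an estimated correlation, and lost its call without delta replicate 3 (adjusted p = 0.0824) and under a stricter filter (0.133). Delta replicate 3 was the library with the raised acinar transcripts.

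Between the alpha- and delta-enriched subsets 3868 genes differed, 1748 higher in alpha and 2120 lower. The balance turned only on TPM, with 798 higher and 618 lower on log2(TPM + 1), 715 and 563 on log2(TPM + 0.1) and 821 and 602 on rescaled TPM. Slc7a2 was at 1898 ± 151 CPM in alpha and 130 ± 31.7 in delta (log2 fold change 3.87, SE 0.16, adjusted p = 2.54e-10, n = 3 each), and the zinc transporter gene Slc30a8 at 900.3 ± 62.9 against a mean of 45.0 CPM (4.32, SE 0.24, adjusted p = 8.66e-07). Bmp3, a secreted signalling factor (ENSMUSG00000029335, chromosome 5, 98854415 to 98884396), was at 0.514 ± 0.364 CPM in alpha and 215 ± 28.9 in delta (-8.69, SE 0.33, adjusted p = 1.78e-10). Rbp4 was lower in alpha (-2.78, SE 0.14, adjusted p = 3.15e-10). Of the tested genes, 5737 (36.1%) had groups that did not overlap, where chance gives 10%.

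By the naming rule the genes furthest higher in alpha were Gm28048 (at least 80.9-fold, 0 counts in delta), Adrb1, the basement membrane genes Lama2 and Nid1, 1110002E22Rik and Igsf21. With 1 to 3 counts in delta, the ratio was 225 for Adrb1 (counting interval 40.1 to 8936), 202 for Lama2 (55.5 to 1670) and 73.3 for 1110002E22Rik (24.8 to 358). Adrb1 moved from 7.36 to 9.22 without delta replicate 3, Lama2 from 7.36 to 10.05 without delta replicate 2, Igsf21 from 5.70 to 6.31 and 1110002E22Rik from 6.04 to 9.19 without delta replicate 3, and Nid1 from 6.20 to 7.42 and 5.62 without delta replicates 1 and 3. Furthest lower were Ppp1r17 (at least 114-fold), Ly6h (at least 105-fold) and Syt6 (at least 84.8-fold), with 0 counts in alpha, then Sst, Spock3 and Bmp3. Sst stood at -8.84 (SE 0.74), or -9.74 without alpha replicate 3. The ratio of delta to alpha for Spock3 was 489.6 (167 to 2377), and its log2 fold change moved from -8.75 to -9.50 without alpha replicate 1.

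Of 14 alpha cell markers 13 were higher in alpha and 1 had no call (adjusted p = 8.74e-24, and adjusted p = 0.00716 with an estimated correlation), among them Irx2 (3.65, SE 0.15) and Gria3 (1.51, SE 0.13). All 7 delta cell markers were lower (adjusted p = 1.2e-16, and adjusted p = 0.00404 with an estimated correlation), with Casr at -1.19 (SE 0.12). Of 14 beta cell markers 10 were higher in alpha than in delta, 2 were lower and 2 had no call, with 12 higher adjusted over the list alone. Papss2 (1.89, SE 0.11) and Ero1lb (2.67, SE 0.20) were higher, and Iapp (-1.84, SE 0.13) and Glp1r (-1.54, SE 0.12) were lower. The list was higher (adjusted p = 2.82e-05), with adjusted p = 0.418 with an estimated correlation. Ins1 and Ins2 were higher in alpha (3.22 and 3.60), missed the threshold in a fit of only these 6 libraries, and came to 4.22 and 4.67 without delta replicate 3. Of 4 PP cell markers 1 was higher, 2 were lower and 1 had no call (adjusted p = 0.443), with a median of -0.37 and a mean of 0.53. Pyy (-1.45, SE 0.13) and Meis2 (-0.98, SE 0.10) were lower, Sertm1 was higher (4.32, SE 0.48, or 4.97 without delta replicate 3), and Ppy stood at 0.24 (SE 0.29). On log2(TPM + 1) Meis2 missed the threshold.

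Receptor genes went both ways between alpha and delta, with 5 of 20 higher in alpha, 10 lower and 5 without a call, or 7 higher and 11 lower adjusted over the list alone (adjusted p = 0.805). The lipid receptor genes Gpr119 (3.56, SE 0.27) and Ffar1 (3.48, SE 0.27) were higher in alpha. In glucose sensing and exocytosis 6 of 17 were higher, 4 lower and 7 without a call (adjusted p = 0.912, median -0.05, mean 0.13), with Abcc8 at -0.67 (SE 0.11), a call lost on log2(TPM + 1). In prohormone processing and granule cargo 7 of 15 were higher, 2 lower and 6 without a call, or 9 higher and 3 lower adjusted over the list alone. The lower genes were the granin genes Chgb (-1.97, SE 0.10) and Scg2 (-1.56, SE 0.11), and Cpe, a carboxypeptidase gene of hormone maturation, was higher (0.97, SE 0.10). That list did not pass (adjusted p = 0.0711), but did without alpha replicate 2 (0.0198), alpha replicate 3 (0.0221) or delta replicate 2 (0.0318), and with no filter on low counts (0.0267). In the unfolded protein response 4 of 17 were lower in alpha and 13 had no call, with 5 lower adjusted over the list alone (adjusted p = 0.214, 0.0494 without alpha replicate 1 and 0.0293 with no filter), and Herpud1 stood at -1.23 (SE 0.19). Of 20 citrate cycle genes 5 were higher, 1 lower and 14 without a call, with 6 higher adjusted over the list alone (adjusted p = 0.214), and Pcx was higher (adjusted p = 1.42e-05). Of 9 genes known as repressed in mature beta cells 5 were higher in alpha, 2 lower and 2 without a call, with 3 lower adjusted over the list alone (adjusted p = 0.38), and Oat (2.41, SE 0.26) and Hk1 (3.13, SE 0.60) were higher.

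Iron genes were examined because CD71 takes up transferrin-bound iron. Between beta and alpha, 8 of 21 tested genes of iron uptake, storage and export were higher in beta, 4 were lower and 9 had no call, with 5 lower adjusted over the list alone. The ferritin light chain gene Ftl1 (ENSMUSG00000050708, chromosome 7, 45457944 to 45459884) was at 423 ± 31.4 CPM in beta and 183 ± 10.6 in alpha (1.21, SE 0.09, adjusted p = 1.96e-08, n = 3 each). Slc40a1, which encodes the iron exporter ferroportin (ENSMUSG00000025993, chromosome 1, 45908068 to 45926523), was at 99.2 ± 7.30 CPM in beta and 193 ± 18.4 in alpha (-0.96, SE 0.13, adjusted p = 1.41e-05). The ferritin heavy chain gene Fth1 (0.64, SE 0.09), Ireb2, which encodes an iron-responsive RNA-binding protein (0.64, SE 0.10), Steap2 (0.57, SE 0.12) and the ferritin receptor gene Ncoa4 (0.42, SE 0.09) were higher. On log2(TPM + 1) Fth1, Ireb2, Steap2, Ncoa4, Tfrc, Hmox1 and Hfe missed the threshold. Of 20 iron genes 1, Ftl1, was then higher in beta and 2, Slc40a1 and Trf, were lower. Fth1 and Ftl1 have many pseudogenes, so their counts are uncertain. The transferrin gene Trf was lower in beta, with 3 counts there and a ratio of 34.4 (counting interval 11.5 to 169), and its log2 fold change of -4.95 moved to -4.31 without beta replicate 1 and -8.30 without beta replicate 3. The list as a whole did not pass (adjusted p = 0.384), with a median of 0.21 and a mean of -0.17, which differ in sign. These counts and tests include Tfrc, which encodes the sort marker. Without Tfrc, a setting chosen after seeing the data, 7 of 20 were higher in beta than in alpha and 4 lower (adjusted p = 0.497).

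Against delta, 10 of 21 iron genes were higher in beta, 2 were lower and 9 had no call (adjusted p = 0.0151, and adjusted p = 0.131 with an estimated correlation), and on log2(TPM + 1) 5 of 20 were higher and 0 lower. Without Tfrc, 9 of 20 were higher and 2 lower (adjusted p = 0.0356, and adjusted p = 0.189 with an estimated correlation). Ireb2 (1.10, SE 0.10), Ftl1 (0.85, SE 0.09), Slc40a1 (1.03, SE 0.13) and the haem oxygenase gene Hmox1 (1.47, SE 0.22) were higher, and the metal transporter gene Slc39a8 was lower (-4.74, SE 0.66). Between alpha and delta, 6 of 21 were higher in alpha, 3 were lower and 12 had no call, with 8 higher adjusted over the list alone (adjusted p = 0.101, 0.0446 without delta replicate 1 and 0.0379 with no filter, or 0.124 without Tfrc). Of the tested iron genes Slc40a1 was furthest higher in alpha (1.99, SE 0.13, adjusted p = 4.29e-09), so that its level ran from 193 CPM in alpha through 99.2 in beta to 48.6 in delta. Steap4, at 2.72 ± 1.66 CPM in alpha with 0 counts in delta, did not pass the count filter and was not tested. Ftl1 was lower in alpha (-0.36, SE 0.09), a call lost on log2(TPM + 1).

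**Figure D3:**
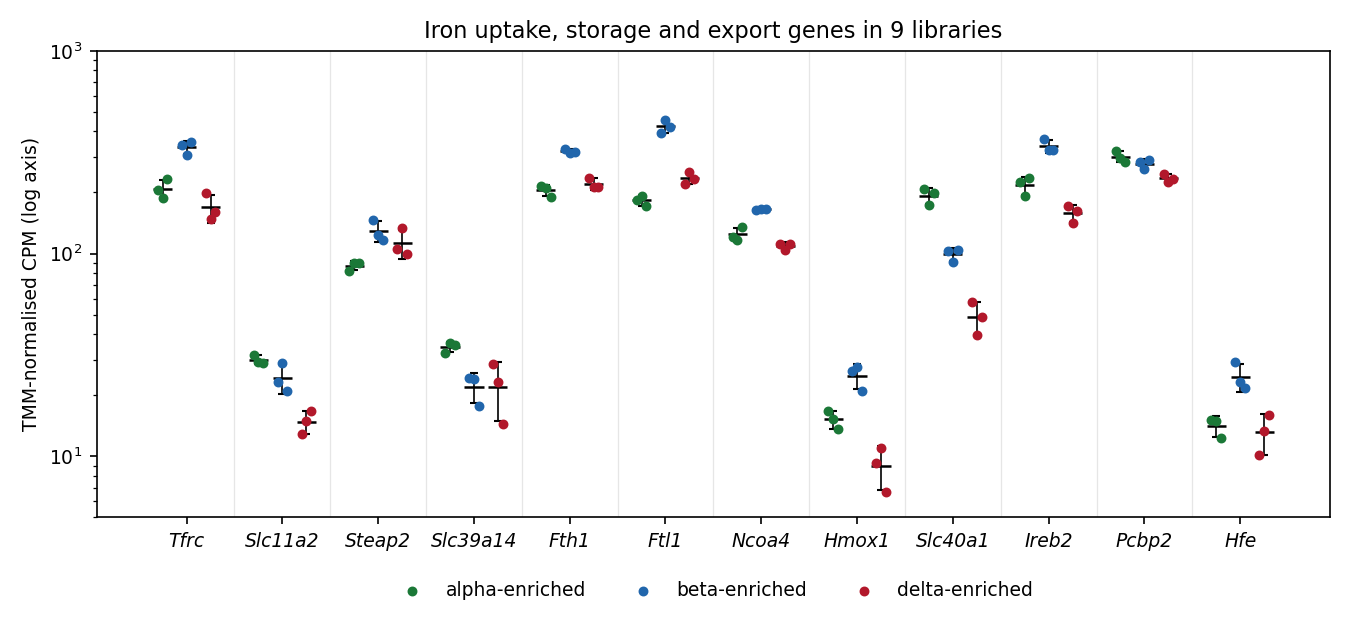
TMM-normalised CPM (log axis) of 12 genes of iron uptake, storage and export in the alpha-, beta- and delta-enriched subsets, with points for libraries, a bar at the mean and error bars of 1 SD (n = 3). Slc40a1 averaged 193 CPM in alpha, 99.2 in beta and 48.6 in delta, and Ftl1 was highest in beta at 423 CPM.

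Genes at least 2-fold higher in 1 subset than in both others numbered 237 for alpha, 403 for beta and 557 for delta, of which 86, 77 and 208 were at least 8-fold higher. The order of beta and delta turned on TPM, with 305 for beta and 257 for delta on log2(TPM + 1), 179 and 124 on log2(TPM + 0.1) and 467 and 222 on rescaled TPM, and with no minimum fold, with 997 and 790. Pdk4, a kinase that inhibits pyruvate dehydrogenase, was at 237 ± 37.5 CPM in alpha, 0.791 ± 0.205 in beta and 10.4 ± 3.80 in delta (adjusted p = 1.5e-08). Sytl2, a granule docking protein gene, was at 104 ± 21.8 CPM in alpha and Higd1a at 38.3 ± 4.62 CPM, with the rest of the named alpha genes being Adrb1, Lama2, Nid1, Igsf21, Pou3f4, Hcar1 and Cyp3a13. In beta, Slc2a2, the glucose transporter gene of beta cells, was at 743 ± 28.2 CPM against 35.8 ± 14.3 in alpha and 6.46 ± 3.98 in delta (adjusted p = 0.0014), Sytl4 at 531 ± 21.8 CPM, Gm17767 at 130 ± 7.14 and Gad1, which makes the transmitter GABA, at 125 ± 11.6. Ucn3, Cib3, Dlgap1, Olfr1322, Gm47824 and Gm6999 completed the beta set. The named delta genes were Sst, Ptprz1, Ghsr, Spock3, Kcnd2, Ppp1r17, Ly6h, Syt6, Cbln4 and Gm45461. On log2(TPM + 0.1) Ucn3, Olfr1322, Adrb1, Lama2, Nid1, Pou3f4, Cyp3a13, Cbln4 and Gm45461 missed the threshold, and Cyp3a13 also missed it in DESeq2.

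Without beta replicate 2 and delta replicate 3 together, chosen after seeing the data, 3231 genes differed between beta and alpha, 3678 between beta and delta and 3278 between alpha and delta, and 207, 327 and 439 genes were enriched in alpha, beta and delta. On log2(TPM + 1) the counts were 1485, 2013 and 1416, and the median log2 fold change of all genes shifted to 0.13 for beta against delta and 0.18 for alpha against delta.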

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

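The lists, tests, naming rule and most alternatives were set before the data were examined. The settings with effective-length factors, the deposited normalised values, rescaled TPM, ribosomal and 7S RNA genes left out, beta replicate 2 and delta replicate 3 left out, or Tfrc left out of the iron list were chosen after seeing the data. In the order beta against alpha, beta against delta and alpha against delta, log2(TPM + 1) gave 1485, 2013 and 1416 genes, log2(TPM + 0.1) gave 1404, 1943 and 1278, and log2(TPM + 1) rescaled without ribosomal and 7S RNA genes gave 1716, 2923 and 1423. These TPM settings also gave 305 beta- and 257 delta-enriched genes for log2(TPM + 1), 105 alpha-, 179 beta- and 124 delta-enriched genes for log2(TPM + 0.1), and 467 beta- and 222 delta-enriched genes for rescaled TPM. None of them scaled TPM between libraries by factors. Limma on the deposited normalised values, which carry a size factor, gave 3070, 3805 and 2934 genes. DESeq2 with effective-length factors gave 3476, 4216 and 3378. Which step lowers the TPM counts was not tested on its own. A test against a log2 fold change of 1 gave 1211, 1468 and 1039 genes, and a minimum log2 fold change of 2 left 155 alpha-, 193 beta- and 325 delta-enriched genes, both stricter by construction. With no minimum fold, 997 genes were enriched in beta and 790 in delta. Directions turned in Atp5b for beta against delta, at -0.010852 with effective-length factors in DESeq2 and -0.007873 on the deposited normalised values, and in Mcm6 for beta against delta, at 0.012162 on rescaled TPM. The cause was not tested. With each library left out in turn, the counts ran from 3210 to 4997 for beta against alpha, 3909 to 5260 for beta against delta and 3090 to 4334 for alpha against delta. Enriched genes ran from 183 to 255 for alpha, 321 to 447 for beta and 485 to 620 for delta. In fits of only the 6 libraries compared the counts were 5321, 4374 and 3165. Beta against alpha then had the most genes, where beta against delta had the most in the main fit. With the replicate number as a replicate block, which the labels do not state as a pairing, the counts were 4625, 5241 and 4294. Same-number libraries correlated at 0.00085 to 0.112 after subset means were removed, and other pairs at -0.102 to 0.021. For each library, the best match within each other subset was also sought. It carried the same number in 16 of 18 cases, which overlap because a pair can count from both sides. This is a hint of shared handling and no proof, and the main tests did not use the block. Of gene-list calls with a preset correlation, 26 in number, 9 held with an estimated one. With no filter on low counts 12 further list calls appeared, with the replicate block 3, in fits of 6 libraries 2 and with upper-quartile factors 1. Leaving out alpha replicate 1 added 8, delta replicate 2 added 4, alpha replicate 3 and delta replicate 1 added 3 each, and alpha replicate 2 and beta replicate 1 added 1 each. Under the stricter filter 24 of the 26 held, and without delta replicate 3 25 held. Without beta replicate 2 and delta replicate 3 together 24 held and 2 appeared. Among settings other than leaving out 1 library, 396 values of named genes lost the call, 3 gained it and 3608 kept call and direction. When 1 library was left out 177 lost it, 2 gained it and 2260 kept both. Simulated changes of 1.5-fold were recovered in only 23.9% of genes with a mean of at least 50 counts. Only 200 of the 15518 simulated genes were changed, while 4231 of 15896 differed in the real data for beta against alpha. Adjustment is stricter where few genes differ, so this recovery does not carry over to the real comparisons. Small differences can still be missed.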

Other observations

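Islet transcription factors divided the subsets in both directions. Pdx1, a factor of beta and delta cells, was at 132 ± 12.7 CPM in beta, 70.9 ± 4.38 in delta and 10.3 ± 2.98 in alpha (beta against alpha, log2 fold change 3.68, SE 0.17, n = 3 each). Neurog3, known for endocrine progenitors, was at 43.0 ± 6.84 CPM in delta, 0.910 ± 0.496 in alpha and 0.222 ± 0.251 in beta. Its log2 fold change for beta against delta was -7.60 (SE 0.48), or -6.92 without beta replicate 1 and -8.88 without beta replicate 3. Neurod1 was higher in alpha (1.38, SE 0.10) and in beta (1.37, SE 0.10) than in delta. Of 18 factors tested, 6 were higher and 6 lower in beta than in alpha, with 9 lower adjusted over the list alone. Against delta, 6 were higher and 9 lower in beta, and 8 higher and 7 lower in alpha, with 9 higher adjusted over the list alone. The list tests did not pass (adjusted p = 0.0638, 0.384 and 0.136). That changed for beta against alpha in a fit of only the 6 libraries (0.00223), with no filter on low counts (0.0348), with upper-quartile factors (0.049) and without alpha replicate 1 (0.0219), delta replicate 1 (0.018) or delta replicate 2 (0.00465), for beta against delta without alpha replicate 1 (0.0418) or 3 (0.0401), and for alpha against delta without delta replicate 2 (0.0138).

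Most protein-coding genes of the mitochondrial genome were lower in delta by the tests of single genes. Of 13, 11 were higher in beta than in delta and 2 had no call (adjusted p = 2.27e-05, and adjusted p = 0.425 with an estimated correlation), with mt-Nd5 at 1.13 (SE 0.11) and mt-Atp6 at 1.23 (SE 0.12), and 11 were higher in alpha than in delta and 2 had no call (adjusted p = 0.000626, and adjusted p = 0.568 with an estimated correlation). As a share of all counts they took 3.68% in beta replicate 2, the library rich in ribosomal RNA, which was below the 3.95% of delta replicate 1. Between beta and alpha 7 were higher in beta (adjusted p = 0.242, 0.0219 without alpha replicate 1 and 0.0323 with no filter). Nuclear genes of the respiratory chain numbered 22, of which 1 was higher in beta than in alpha, 6 in beta than in delta and 2 in alpha than in delta, or 0, 1 and 0 adjusted over the list alone (adjusted p = 0.661, 0.345 and 0.497). Of 15 glycolysis genes 6 were higher and 1 lower in beta than in alpha (adjusted p = 0.0815, 0.00945 without beta replicate 1, 0.0188 with the replicate block and 0.00452 with no filter), with the pyruvate kinase gene Pkm at 0.89 (SE 0.12). Against delta 5 were higher and 2 lower in beta, 6 higher adjusted over the list alone (adjusted p = 0.567, median 0.16, mean -0.04), and 5 were lower in alpha, 6 over the list alone (adjusted p = 0.278, and 0.0484 with no filter). Of 21 genes of iron-sulfur cluster assembly 4 were higher in beta than in alpha (2 adjusted over the list alone), 1 was higher in beta than in delta and 1 was lower in alpha than in delta (0 over the list alone), with the chaperone gene Hspa9 at 0.70 (SE 0.13) against alpha and 0.84 (SE 0.13) against delta (adjusted p = 0.443, 0.61 and 0.823). Of 8 haem synthesis genes 1 was higher in beta than in alpha, 2 were higher in beta than in delta and 1 was higher in alpha than in delta (0 adjusted over the list alone), with Cpox higher in beta than in alpha (0.78, SE 0.15) and than in delta (edgeR adjusted p = 5.47e-06) (list adjusted p = 0.693, 0.38 and 0.497). Of 10 cell cycle genes 1 was higher in beta than in alpha, 1 was higher and 1 lower in beta than in delta, and 3 were lower in alpha than in delta (adjusted p = 0.278, 0.661 and 0.514, the first 0.0323 with no filter). Of 14 immediate early and dissociation genes 1 was lower in beta than in alpha (adjusted p = 0.807, median 0.18, mean -0.13), 3 were lower in beta than in delta (0.278) and 2 lower in alpha than in delta, or 1 over the list alone (0.298, and 0.0184 without alpha replicate 1), with Ier2 at -2.35 (SE 0.34) for beta against delta. With the replicate number as a block and the preset correlation this list passed as lower in beta than in delta (0.00636) and in alpha than in delta (0.00295). An estimated correlation, used only without the block, gave a camera adjusted p = 0.773 in both comparisons. A difference in handling stress between delta and the others is not ruled out.

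Markers of other cell types were measured in every subset. Duct cell markers summed to 5298 to 5856 counts per alpha library, 2199 to 3009 per beta and 1256 to 2726 per delta library. The highest delta sum was in delta replicate 3, the library with the raised acinar transcripts, against 1589 and 1256 in the others. There Krt19 had 47 counts, against 0 and 7, and Anxa3 58, against 0 and 0. Cftr had 9, against 2 and 9. These genes were named after their values were seen. The alpha sum was mostly Spp1, at 557 ± 104 CPM in alpha, 110 ± 49.1 in beta and 78.4 ± 51.4 in delta, whose call for beta against alpha was lost without alpha replicate 2 or 3, without beta replicate 1 or 3 and with the replicate block. The duct factor Sox9 went with the CD24-high subset, at 19.0 ± 5.48 CPM in delta and 0.544 ± 0.565 in alpha, with 0 counts in beta (at least 127-fold lower in beta than in delta), and its call for beta against alpha was lost with any library but alpha replicate 1 left out. Of 5 tested, Krt7 was higher in beta, at 251 ± 26.3 CPM, than in alpha, at 125 ± 8.49, and than in delta (log2 fold change 1.09, SE 0.12), while 3 were lower than in alpha and 2 lower than in delta, and 1 was higher and 1 lower in alpha than in delta (adjusted p = 0.708, 0.657 and 0.693, the last with a median of 0.02 and a mean of -0.49). Of 10 acinar markers tested 1 was lower in beta than in alpha, 1 in beta than in delta and 1 in alpha than in delta (adjusted p = 0.278, 0.0677 and 0.235). The acinar list passed for beta against delta without alpha replicate 1 (0.0109), alpha replicate 3 (0.0389), delta replicate 1 (0.0384) or delta replicate 2 (0.0199), in a fit of only the 6 libraries (0.0202) and with no filter (0.00315), and for alpha against delta without alpha replicate 1 (0.0184) and with no filter (0.0348). Alpha replicate 1 also held more acinar transcripts than the other alpha libraries, with Pnlip at 81.5 CPM against 2.77 and 7.90. Mesenchymal markers summed to 118, 414 and 120 counts in alpha replicates 1 to 3, against 9 to 10 in beta and 24 to 71 in delta. The basement membrane genes Lama2 and Nid1, named among those furthest higher in alpha, were highest in alpha replicate 1 (25.9 CPM) and alpha replicate 2 (19.1 CPM), and their source was not tested. Of 2 tested, 1 was lower in beta than in alpha (2 adjusted over the list alone), 2 were lower in beta than in delta and 1 was higher in alpha than in delta (adjusted p = 0.125, 0.439 and 0.384, the first 0.0184 without alpha replicate 1, and the first and last 0.0128 and 0.0348 with no filter). Of 2 Schwann cell markers tested 0 differed between beta and alpha, 2 were lower in beta than in delta and 1 was lower in alpha than in delta (adjusted p = 0.693, 0.294 and 0.403). Endothelial, immune and erythroid markers summed to at most 89, 99 and 19 counts in any library.

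The tests below on insulin, on Ppy and Pyy and on acinar transcripts were chosen after the result was seen, and those on other splits of the libraries before. For each pairwise comparison the 6 libraries can be split in only 10 ways, too few for a share under 0.05. The real split was the only 1 of the 10 with as many genes, at 4231 for beta against alpha, 4869 for beta against delta and 3868 for alpha against delta, with a highest other count of 0 in each. For lists past the test, 3 of the 10 splits gave as many for beta against alpha (real 10, highest other 13), 1 of 10 for beta against delta (real 12, highest other 8) and 8 of 10 for alpha against delta (real 4, highest other 7), again too few splits. Mixed splits thus also called lists with the preset correlation. Each of their groups held libraries of both subsets in unequal numbers, so part of the real difference stayed in them. These list counts therefore cannot separate chance from the difference between subsets. For enriched genes, 100 partitions of the 9 libraries were counted. Only the real one (1 of 100) gave as many genes as beta (403) or delta (557), with a highest other of 281. For alpha (237) 6 of 100 gave as many, so chance is not excluded by this count. All 5 of the others kept the real beta or delta subset together, since each partition was counted by the highest of its groups. Partitions that kept the alpha subset together gave 73 to 79 genes. The 89 partitions that kept none together gave 0 genes. Groups that mix libraries of different subsets have a wider spread, so these counts cannot decide on chance for any subset.

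Ins2 stood in the alpha-enriched libraries at 8.96 ± 1.52% of its beta level and Ins1 at 8.25 ± 2.18%. Reads of the beta libraries assigned to other libraries of the run are argued against, since the alpha share of Ins2 was 12.16 times the delta share. Beta cells or their RNA in the alpha gate are a candidate explanation that stays open for part of this Ins2. Of 44 abundant beta genes, 15.91% lay below the lowest Ins2 share in every alpha library, such as Slc2a2 at 4.82% and Ucn3 at 4.11%. That lies between 5% and 25%, bounds chosen after the result was seen for allowing and for excluding such cells. The bounds have no other basis, so this share of genes does not decide whether such cells were present. Cells with the full beta-enriched profile would put every beta gene at or above the share they add. The 7 genes below the lowest Ins2 share, with Gm17767 lowest at 3.36 ± 1.10%, therefore argue against such cells as the source of all the Ins2. Most of the 44 genes did not lie below it, so a part from such cells stays open. Beta cells low in CD71 with another profile, which the gate would admit, stay open and untested.

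Ppy stood in the delta-enriched libraries at 84.8 ± 18.8% and Pyy at 273 ± 52.5% of the alpha level, while Gcg stood at 4.90 ± 2.42%. Carry-over of alpha-enriched cells or their RNA is argued against, since the smaller of the Ppy and Pyy shares was at least 10.91 times the Gcg share in every delta library. PP cells sorted into both gates stay open. The PP cell marker Sertm1 stood in the delta libraries at only 4.84 ± 3.18% of its alpha level, but this was 0.9867 times the Gcg share, so the Sertm1 of the alpha libraries could come from alpha cells and its low share does not decide. Pyy and Ppy expressed by delta cells themselves stay open and untested.

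Acinar enzyme transcripts were raised in delta replicate 3, with Pnlip at 315 CPM, Ctrb1 at 302 and Cpa1 at 269, and 10 of 10 tested acinar genes were highest in that library. This count largely restates the rise that prompted it and is no independent support for a source. Acinar cells or their RNA in that library are a candidate source, and the picking of islets by hand and the CD24 gate are the steps that could remove them. For 9 of the 10 the level there was 7.98 to 45.6 times the higher of the other delta libraries. No biological explanation of the acinar transcripts in this library was tested.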
